A study of Mus musculus with 2 samples.

How the data were processed

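DNase-seq libraries of kidney from male B6CASTF1/J mice aged 10 days were compared as 1 group of 2 biological replicates, numbered as in the labels. Both carry 1 donor label, and nothing in the sources used here says that the tissue came from separate litters. The label of replicate 1 lists 2 models of sequencing instrument, and that of replicate 2 lists no instrument. Per the text listings deposited with each library, the peaks, footprints and cut-rate files were derived from that library's own alignments to mm10 and were not pooled. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. B6CASTF1/J animals carry genomes of different strains, and the files hold reference coordinates only, so alleles were not analysed here.

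Each library had 2 deposited peak lists. The deposited signal of each peak is a tag density that the authors' listing calls normalised for read depth, and it was a whole multiple of 1 step per library (0.004538 in replicate 1 and 0.003073 in replicate 2) for 100% of peaks within 0.02 of a step. It was used only to describe and rank peaks within a list. The deposited cut-rate files give a false discovery rate, an adjusted p-value computed by the authors, for stretches of bases under 0.05, covering 57.7 Mb and 69.3 Mb. Checked against them, the lowest rate under every peak of the longer lists was under 0.05 and under every peak of the shorter lists under 0.001. The deposited footprints carry the constant p-value threshold 0.01.

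Before the data were examined, the design, the gene lists, the consensus sequences, the rule for named genes and most alternatives were fixed. The design took the peak list with the narrower median width as the main one. This rule gave a tie, since the median was 180 bp in all lists, and after the data were seen the tie was broken by mean width: 188.4 and 185.0 bp for the longer lists against 191.1 and 188.5 bp for the shorter ones. The longer lists, at a false discovery rate of 0.05, are therefore the main lists. The alternatives chosen after seeing the data were the shorter lists (rate 0.001) for the gene lists and named genes, and leaving out each replicate for the number of footprints. A margin from 200 bootstrap draws was also added after the first values of the exon test in the closing section had been seen; both outcomes were the same with and without it.

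Coordinates and sequences were taken from the mouse reference GRCm38 with its GENCODE annotation, whose chromosome lengths hold all peaks and footprints. Promoters were windows of 1000 bp around 41438 annotated starts of 21851 protein-coding genes. Peaks were put in the first class that applied of promoter, exon, intron and intergenic. Overlaps needed at least 1 bp, and random placement used 10 draws clear of assembly gaps. A shared region is a merged region with a peak of both libraries. Shares carry exact (Clopper-Pearson) binomial 95% intervals, which cover counting error only.

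The 22 fixed lists held 322 symbols, of which 321 were found in the annotation, and Amy2b was not. Olfactory receptor genes, taken by symbol, were added as a negative control, giving 23 lists in each of the promoter and distal families. A list's value was placed by mid-rank among 10000 random lists of its size. They were matched on the decile of promoter CpG observed over expected for promoters and of gene length for distal regions. CpG content was taken around the outermost start of each gene, whereas a peak at any annotated start counted as a promoter peak. The number of starts per gene was not matched, so genes with more starts had more windows in which to be open. The 1134 olfactory receptor genes were placed among 1000 lists drawn with replacement from other genes. Percentiles of 97.5 and 2.5 were the bounds. With 1 group there is no contrast between conditions, and no p-value was computed. From each list the 2 members with the best-ranked promoter peak (mean percentile of peak density over the libraries) and up to 2 members, by alphabet, without a promoter peak were named. Also named were the 10 genes with the most distal shared regions, the 5 best-ranked distal peaks, all consensus sequences with a ratio over 1.5 in both libraries and the 5 lowest. Some items that this rule names are not reported here. The repeat count of a named distal peak is the number of genomic occurrences of its central 36 bases.

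Consensus sequences (37) were searched on both strands in footprints and in the other bases of the peaks. Footprints outside peaks were included, and in every search an occurrence was placed by its centre base. The ratio of occurrences per kb of each sequence carries a Poisson 95% interval. It stands beside the median of up to 10 different shuffled versions (8 for SP or KLF). In a further search for the closing section, 5 of these sequences were counted around each of the 22 fixed lists, which makes 110 combinations.

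The steps were tested on simulated data. For promoter lists of 15 from the 4 lowest CpG deciles among 21851 genes, 97.5% of 200 lists with 2 of every 3 closed promoters opened reached the upper bound, and 2.5% of 200 unchanged lists did. For distal lists of 15, 65% of lists with doubled counts and 1.5% of unchanged lists did. Promoter lists from the higher CpG deciles were not simulated. Of 20000 simulated intervals, 80.25% were made to overlap and 80.25% were found, and a planted consensus ratio of 5.00 was found as 4.94. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9 and bedtools 2.31.1 were used. The alternatives were other overlap rules, stricter or shorter peak lists, other promoter windows and flanks, no CpG matching, another background for the consensus sequences, and each replicate left out.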

Results

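Accessible chromatin was mapped by DNase-seq, in which DNase I cuts nuclear DNA preferentially where it is not covered by nucleosomes, in whole kidney tissue of male B6CASTF1/J mice aged 10 days. The labels place both libraries in 1 group as biological replicates 1 and 2, so the comparisons below are between the replicates and between gene groups, genomic classes and sequence motifs within them. Both biosamples carry the same donor label, and their descriptions read 3x Males without explanation. Whether a library holds tissue of 1 or several animals is therefore not known, and the spread between the libraries may differ from that between single unrelated animals. A DNase I hypersensitive site (DHS) is a called peak, and a footprint is a short protected stretch. Replicate 1 had 191115 peaks and replicate 2 had 234619, a mean of 212867 ± 30762 (SD, n = 2). The total number of reads is not known from these sources. The smallest step of the deposited peak density was 1.48 times finer in replicate 2, and all densities were whole multiples of that step within a tolerance of 0.02 of a step. Densities are given below in these steps, and their scale differs between the libraries.

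The kidney DHS map covered 35.7 Mb in replicate 1 and 42.9 Mb in replicate 2, which is 1.35% and 1.62% of the ungapped mouse genome (mm10). The median peak was 180 bp wide in both libraries and reached a density of 134 steps in replicate 1 and 155 steps in replicate 2. Of the replicate 1 peaks, 80.9% overlapped a replicate 2 peak (exact binomial 95% interval 80.7 to 81.1%), and of the replicate 2 peaks 66.2% overlapped a replicate 1 peak (65.96 to 66.34%). The same peaks placed at random on their own chromosomes met a peak of the other library in 3.45% and 2.84% of cases. Merging gave 265366 regions, of which 151651 were found in both libraries. When the same number of best-scored peaks was taken from each library, the shares were 75.9% and 76.2%.

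Strong sites were found in both libraries and weak sites were often found in 1. In the top score decile 99.4% of replicate 1 peaks and 99.0% of replicate 2 peaks were shared, and in the lowest decile 41.1% and 13.5% were. Shared peaks had a median density of 166 steps in replicate 1 against 67 steps for peaks that were not shared, and of 240 against 84 steps in replicate 2. These intervals cover counting error only.

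**Figure D1:**
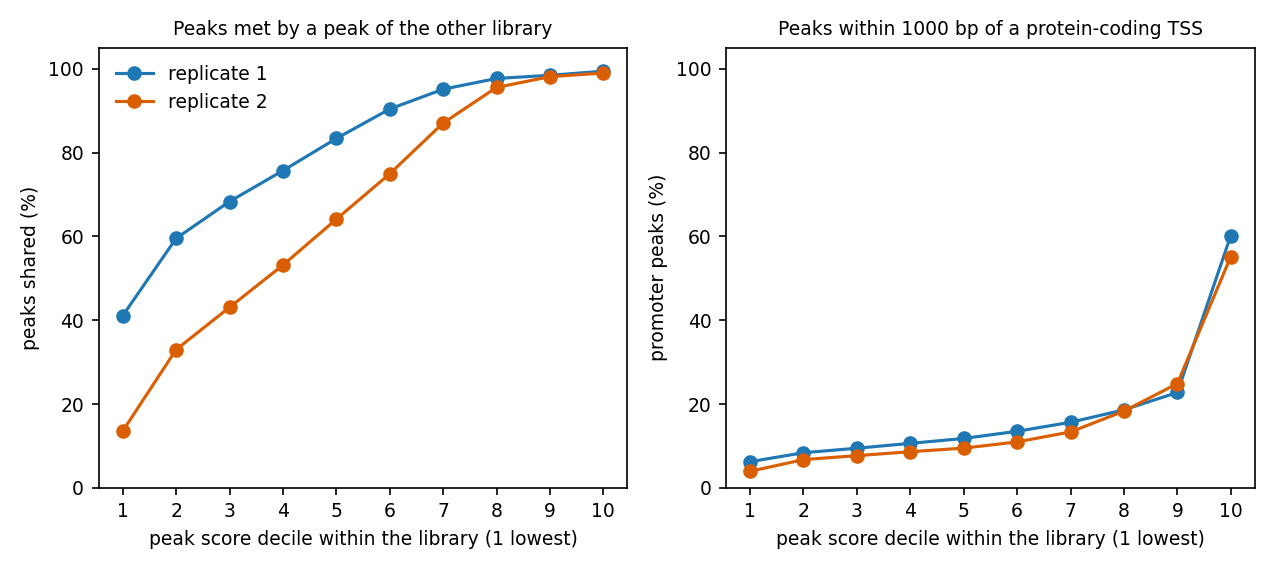
Share of peaks met by a peak of the other library (left, %) and share of peaks within 1000 bp of a protein-coding transcription start (right, %) by decile of the authors' peak density within each library, with 1 point per library and decile. Sharing runs from 41.1% to 99.4% in replicate 1 and from 13.5% to 99.0% in replicate 2, and the promoter share reaches 60.15% and 55.15% in the top decile.

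Promoters were the class most enriched in DHSs relative to random placement. Within 1000 bp of a transcription start site (TSS) of a protein-coding gene lay 17.7% of replicate 1 peaks and 15.9% of replicate 2 peaks (mean 16.8% ± 1.27, SD, n = 2), against 2.37% of randomly placed peaks, which is 7.46-fold and 6.71-fold. Exons outside promoters held 7.26% and 8.53% of peaks against 4.49% and 4.48% at random. Introns held 41.4% and 41.6%, close to the 42.2% of random placement, and intergenic sequence held 33.6% and 33.9% against 50.9%. Among peaks shared by the libraries, 19.35% of those in replicate 1 and 19.33% of those in replicate 2 were at promoters, compared with 10.8% and 9.22% of peaks that were not shared. Exonic sites made up 10.9% of the peaks found in replicate 2 alone and 7.28% of those found in replicate 1 alone. The promoter share depends on its definition and was 12.7% with a window of 500 bp and 22.7% with 2500 bp, as means of the libraries.

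Of 21851 protein-coding genes, 15297 (70.0%) had a promoter DHS in both kidney libraries, 225 in replicate 1 alone, 746 in replicate 2 alone and 5583 in neither. CpG-rich promoters were open almost throughout: 98.8% of genes in the highest decile of CpG content had a DHS in both libraries, against 8.92% in the lowest. Gene lists were therefore compared with 10000 random lists of the same size and CpG deciles, which describes these libraries and gives no p-value. The deciles are those of each gene's outermost start, also where the open start is another one, and the number of starts was not matched.

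Several lists of nephron genes were open more often than such random lists, among them those of the proximal tubule and the thick ascending limb. Among 26 proximal tubule genes 23 had a promoter DHS in both libraries (88.5%, against a mean of 53.4% in random lists, a rounded percentile of 100). The thick ascending limb list had 11 of 12 (percentile 99.8), the distal convoluted tubule list 9 of 10 (98.9) and the collecting duct principal cell list 11 of 11 (percentile 99.96). For intercalated cells, the acid-base cells of the collecting duct, 10 of 13 promoters were open, at percentile 96.7. All 15 podocyte genes (97.7) and all 27 kidney transcription factor genes (99.1) had a promoter DHS in both libraries. The podocyte genes Col4a3 and Col4a4 were open through the same peak in each library, so that peak counted for both of them. The nephron progenitor list had 11 of 12, near the middle of the random lists (percentile 46). Those lists averaged 91.8% open, and with all 12 open in replicate 2 the nephron progenitor list stood at 75.8 in that library. It therefore had little room to reach the upper bound. All 15 stromal genes and all 15 endothelial genes were open (percentiles 100 and 99.98). Across 7 other settings, the proximal tubule, stroma and endothelium lists stayed at or above the upper bound of the central 95% of random lists in each. The thick ascending limb list did so in 6 (95.3 without CpG matching), the principal cell list in 5 (94.1 in the better-scored part of each peak list and 91.1 in the shorter lists), the kidney transcription factor list in 5 (95.8 with a window of 500 bp and 97.3 without replicate 1) and the distal convoluted tubule and podocyte lists in 3 each, with lowest percentiles of 31.3 and 82.7 in the better-scored part. The intercalated cell list reached that bound in 2 and had its lowest percentile, 24.4, in the better-scored part. All 15 podocyte genes stayed open with a window of 2500 bp (95.25) and without replicate 1 (95.05) or 2 (97.25). So did all 27 transcription factor genes without replicate 1. Those percentiles were the highest possible there, so the bound could not be reached in these settings.

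The strongest promoter peaks of the tubule lists included transport genes used along the nephron. Among proximal tubule genes, the best-ranked were those of the water channel Aqp1 (chromosome 6, 55335981 to 55336440 in replicate 1), at the 95.1 and 91.2 percentiles of peak density in replicates 1 and 2, and of Ass1, which encodes argininosuccinate synthase, at 92.5 and 93.7. In the thick ascending limb list they were those of Egf, at 97.6 and 97.4, and Enox1, at 87.1 and 91.0 for different peaks, 1028 bp from its start in replicate 1 and 22 bp from it in replicate 2. The Egf peak lies 24 bp from an annotated start inside the gene, 30205 bp from its outermost start. Cnnm2, a gene of magnesium handling, had the highest-ranked promoter of the distal convoluted tubule list (chromosome 19, 46761281 to 46761560 in replicate 1, percentiles 99.96 and 99.94), followed by the potassium channel gene Kcnj10 at 90.4 and 93.1. The sodium channel subunit gene Scnn1g stood at 91.4 and 94.6 and St6gal1 at 89.0 and 92.3 among principal cell genes. Car2, encoding a carbonic anhydrase, stood at 82.8 and 92.9 and the ammonium transporter gene Rhbg at 76.4 and 88.1 among intercalated cell genes.

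Among podocyte genes the promoter of Cd2ap (98.0 and 99.4) ranked highest, and among nephron progenitor genes that of Sall1 (88.6 and 93.2). Ppara (97.6 and 98.7) and Foxc2 (97.7 and 96.4) led the transcription factors, Meis1 (97.15 and 94.73) and the collagen gene Col1a1 (94.4 and 97.3) the stroma, and Ehd3 (97.4 and 96.8) and the VEGF receptor gene Kdr (91.6 and 94.8) the endothelium. No promoter peak was found in either library for the tubule genes Slc22a8, Slc7a13, Tmem207, Slc8a1, Aqp6 and Slc4a1. With a window of 2500 bp, Slc22a8, Slc7a13 and Tmem207 had a peak in 2 libraries and Aqp6 and Slc8a1 in 1.

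Promoters of genes used in other organs and cell types were open no more often than the random lists, and in 3 lists less often. Of 12 erythroid genes 2 were open in both libraries (percentile 0.51), of 12 germ cell genes 1 (Dazl) and of 1134 olfactory receptor genes 30, the latter lists lying below all random lists (percentile 0). The germ cell list had 1 open member in replicate 1 and 4 in replicate 2, the olfactory receptor list 50 and 64, and the erythroid list stood at percentile 3.81 in the better-scored part of each peak list, inside the central 95% of random lists. The immune list had 4 of 15 (percentile 14.8), adrenal gland 3 of 13 (13.9), adipocyte 5 of 12 (22.4), liver 6 of 18 (43.5), neuron 11 of 16 (6.06), striated muscle 6 of 16 (11.96), pancreas 4 of 13 (5.84) and lung epithelium 3 of 12 (3.68). Single libraries moved these lists: without replicate 2 the immune share was 46.7% (percentile 65.8) in place of 26.7%, and without replicate 1 the lung share was 41.7% (29.2) in place of 25%, the neuron list stood at percentile 54.3 and the striated muscle list at 55.1. Other settings put lists below the central 95%: neuron (0.005), striated muscle (1.015) and pancreas (0.72) in the better-scored part, neuron (0.03) and pancreas (0.26) in the shorter lists, adrenal gland (0.495), lung (0.51) and striated muscle (1.315) with a window of 500 bp, and immune (0.035), adrenal gland (0.06), liver (0.085), striated muscle (0.42), pancreas (0.335) and lung (0.085) without CpG matching. All 14 housekeeping genes (percentile 83.6) and all 12 cell cycle genes (70.7) were open, within the central 95% of random lists of their CpG content. With every member open, these percentiles were the highest possible in this comparison, so neither list could reach the upper bound.

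The best-ranked promoter peaks of these lists ranged from near the top of the libraries to the middle, as for Ins2 in replicate 1. Rplp0 and Ywhaz (99.8 and 99.8, and 99.6 and 99.7) led the housekeeping list, and Ccna2 (99.4 and 99.6) and Mcm5 (99.5 and 99.4) the cell cycle list. Cd68 (76.3 and 67.9) and Lyz2 (72.9 and 62.7) led the immune list, Epor (90.0 and 91.3) the erythroid list, Chga (88.6 and 96.9) and Star (66.5 and 80.4) the adrenal list, and Lipe (98.3 and 98.9) and Cidea (70.6 and 84.5) the adipocyte list. Itih1 (72.5 and 89.1) and Apob (72.2 and 88.8) led the liver list, Snap25 (86.5 and 95.5) and Bcl11b (86.9 and 90.8) the neuron list, Mylpf (98.8 and 98.1) and Actn2 (88.2 and 89.5) the muscle list, Nkx6-1 (89.8 and 91.2) and Ins2 (50.1 and 65.3) the pancreas list, Abca3 (96.3 and 97.7) and Foxf1 (83.1 and 89.7) the lung list and Dazl (95.6 and 96.5) the germ cell list. The Ins2 peak lies 21 bp from an annotated start inside the gene, 43850 bp from the outermost one, and the Lipe peak lies 678 bp from its nearest annotated start and 3009 bp from the outermost one in replicate 1. Among genes without a promoter peak in either library were Adgre1 (immune), Alas2 and Epb42 (erythroid), Cyp11a1 and Cyp11b1 (adrenal), Adipoq and Cfd (adipocyte), Ahsg and Alb (liver), Neurod2 and Neurod6 (neuron), Ckm and Myh6 (muscle), Cel and Cela2a (pancreas), Lamp3 and Scgb1a1 (lung) and Acrv1 and Mael (germ cells). With a window of 500 bp the Star promoter had a peak in 0 libraries, and with 2500 bp that of Cfd had one in 2.

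**Figure D2:**
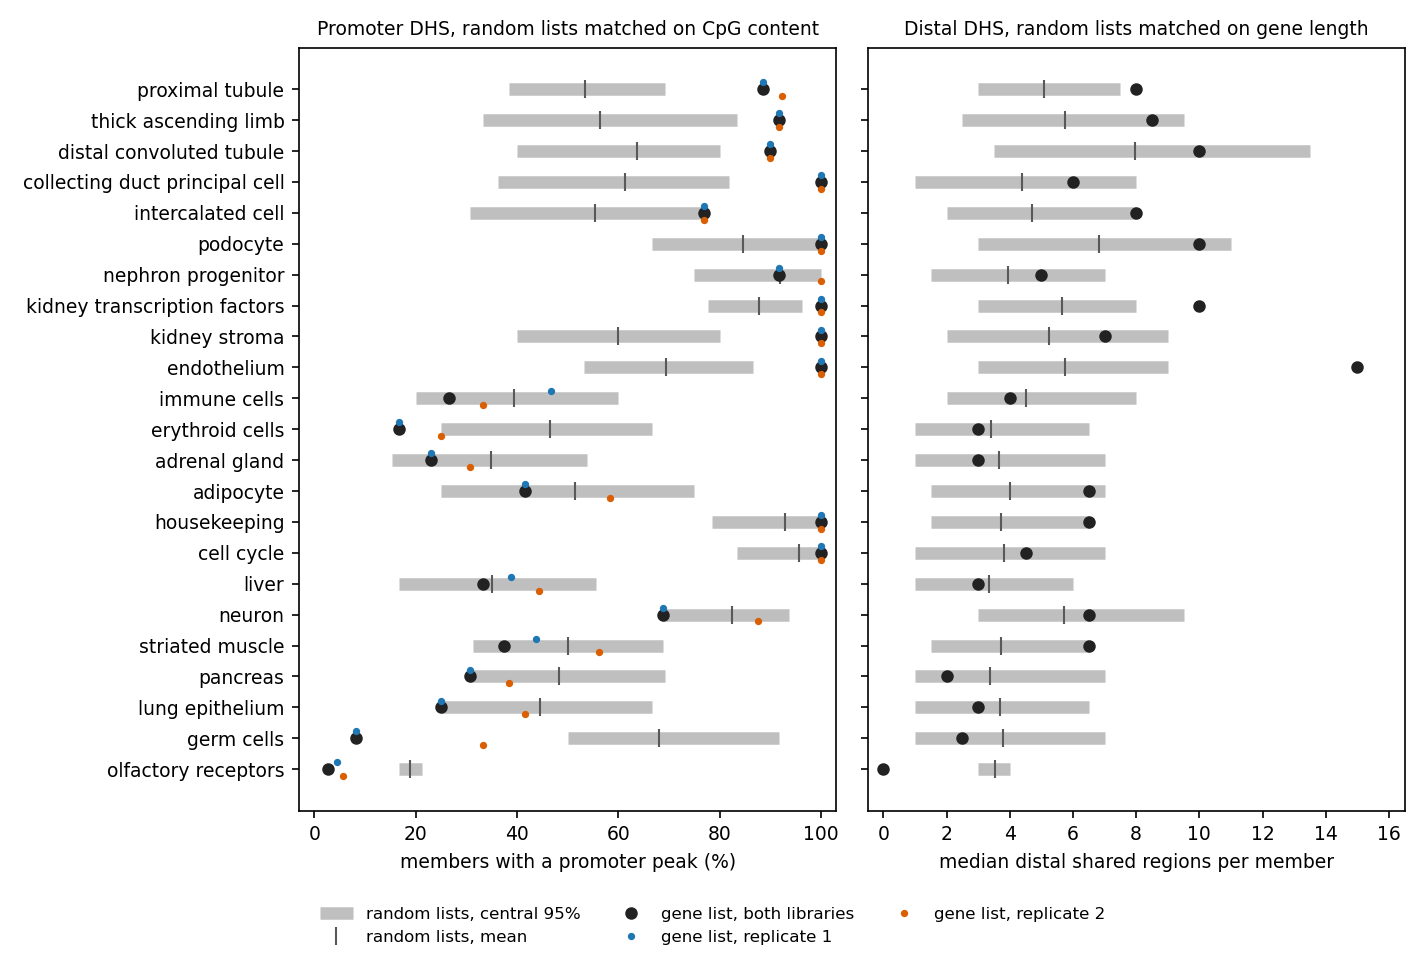
Share of each gene list's members with a promoter peak (left, %) and median number of distal regions shared by both libraries per member (right), as black points, with grey bars for the central 95% of random lists and small points for each library. The endothelium list stands at 100% on the left and at 15 regions on the right, and the germ cell list at 8.33% on the left.

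Away from promoters, endothelial, kidney transcription factor and proximal tubule genes had more DHSs around them than random lists. The median endothelial gene had 15 regions shared by both libraries in its body and 25 kb on either side, against a mean median of 5.74 in random lists of the same gene length deciles (percentile 100). The median kidney transcription factor gene had 10 (percentile 99.7) and the median proximal tubule gene 8 (98.6). Striated muscle and housekeeping genes had medians of 6.5 (percentiles 97.45 and 97.41), intercalated cell genes 8 (96.8), adipocyte genes 6.5 (94.0), podocyte genes 10 (92.8) and thick ascending limb genes 8.5 (92.4). Lower percentiles were found for kidney stroma (median 7, percentile 85.15), principal cell (6, 82.3), distal convoluted tubule (10, 79.3), nephron progenitor (5, 76.8), neuron (6.5, 70.6), cell cycle (4.5, 69.1), liver (3, 41.2), erythroid (3, 41.1), immune (4, 38.9), adrenal (3, 34.5), lung (3, 33.15), germ cell (2.5, 19.8) and pancreas genes (2, 19.6). Olfactory receptor genes had a median of 0 (percentile 0). With 100 kb on either side, the percentiles of the endothelium, proximal tubule and kidney transcription factor lists were 93.4, 96.8 and 95.9. Counting the regions of replicate 2 alone raised the median by over 1.5 times for proximal tubule (14), principal cell (11), podocyte (16), nephron progenitor (11, percentile 97.1), immune (7), housekeeping (11, percentile 99.0), cell cycle (7), neuron (10.5), pancreas (6) and lung genes (5.5), and counting those of replicate 1 alone did so for adrenal (6, percentile 79.5) and germ cell genes (4). The proximal tubule list stood at 89.5 with the gene body alone and the endothelium list at 97.44 in the better-scored part of each peak list. Of 6 other settings, the kidney transcription factor list reached the upper bound in 5 and the endothelium and proximal tubule lists in 4 each. The housekeeping list did so in 3, and the podocyte, nephron progenitor, stroma and cell cycle lists in 1 each.

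The genes with the most distal shared regions were long ones. Gm20388 on chromosome 8, whose annotation spans 4435 kb and many other genes, had 649, and Fgfr2, annotated over 2961 kb of chromosome 7, had 245. Gse1 followed with 102, Lrmda with 101, Pde4d with 94, Camta1 and Nav2 with 90 each, Bcas3 and Tns1 with 83 each and Rora with 82. Tns1 was the shortest of these, at 214.2 kb. The best-ranked distal DHS lay in an intron of Mid1 (X, 169998041 to 169998420), where the central 36 bases occur 6 times in the genome. Intergenic DHSs followed on chromosome 16 (4541861 to 4542080, nearest to Tfap4 at 17883 bp), on chromosome 5 (25529581 to 25529880, nearest to Cct8l1 at 13664 bp) and on chromosome 13 (107890101 to 107890420, nearest to Smim15 at 154185 bp), and then a DHS in a ribosomal RNA gene on chromosome 17 (39846781 to 39846900), whose central sequence occurs 2 times. The aligner is not known here, so whether reads from other copies add to the Mid1 and ribosomal RNA sites cannot be told.

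The X chromosome carried fewer DHSs than the autosomes in these male mice. Replicate 1 had 29.4 peaks per Mb on X and 77.7 on the autosomes, and replicate 2 had 35.8 and 95.4, a ratio of 0.377 ± 0.0019 (SD, n = 2). The Y chromosome had 79 and 173 peaks. Among the better-scored part of each list the X ratio was 0.225.

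Footprints numbered 486789 in replicate 1 and 679493 in replicate 2 (mean 583141 ± 136262, SD, n = 2), with median widths of 10 and 11 bp. Of these, 87.0% and 83.9% lay in peaks of the same library, and 26.2% and 26.9% were at promoters. A footprint of the other library overlapped 64.9% of those in replicate 1 and 44.0% of those in replicate 2. Inside peaks the shares were 64.12% and 45.35%, against 42.7% and 32.1% for footprints placed at random within the same peaks. When an overlap of at least 50% of both footprints was required, 43.3% and 31.0% were shared.

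Recognition sequences of CTCF, of general promoter factors and of HNF4 were concentrated in the footprints. Of 37 consensus sequences, 17 occurred more than 1.5 times as often per kb in footprints as in peak bases outside footprints in both libraries. In both, 15 occurred less often in footprints than in those bases. Footprints that lie outside peaks were counted too. The NRF1 consensus had the highest ratio in replicate 1, 81.8 (Poisson 95% interval 55.1 to 126.5), with 41.2 in replicate 2 (29.8 to 58.4), and CTCF, the insulator protein, the highest in replicate 2, 56.5 (51.2 to 62.5), with 36.35 in replicate 1 (33.65 to 39.31). Those of NFI were 19.8 and 34.0, of RFX 22.15 and 21.64 from 29 and 32 footprinted sites, of SP or KLF 12.5 and 13.3, and of CREB 11.7 and 12.4. The direct repeat bound by HNF4, PPAR or RXR had ratios of 10.2 and 6.76 and the shorter HNF4 consensus 2.47 (2.33 to 2.61) and 2.03 (1.92 to 2.15), against 0.63 and 0.66 for its shuffled versions. HNF1, a factor of tubule epithelium, had 1.94 (1.28 to 2.90) and 1.84 (1.20 to 2.79) from 36 and 37 footprinted sites, while its highest shuffled version reached 2.705 in replicate 2. ESRR had 1.69 and 1.62, with highest shuffled versions of 1.24 and 0.99.

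The remaining sequences over 1.5 were YY1 (8.23 and 7.47), ETS (5.05 and 4.49), E2F (4.77 and 4.55), REST (4.22 and 3.58), NEUROD (2.78 and 2.44), the E-box of USF or MYC (2.11 and 1.82) and TFAP2 (2.10 and 2.25). The NEUROD sequence also occurs within some forms of the CTCF sequence. CTCF sites were not taken out of its count, so its ratios may partly be those of CTCF. Shuffled TFAP2 sequences had higher median ratios, 2.51 and 2.87, so TFAP2 stood out no more than its base composition. Shuffled SP or KLF sequences had 6.54 and 7.96, below the ratios of the sequence itself, and shuffled E-boxes had 1.65 and 1.67 and reached 3.16 and 2.64, above the ratios of the E-box itself. Among the lowest ratios were those of FOX (0.23 and 0.27, with shuffled medians of 0.38 and 0.46), the glucocorticoid receptor (0.37 and 0.30, with 1.04 and 0.89), the flanked GATA sequence (0.33 and 0.40, with 0.49 and 0.54) and GATA (0.43 and 0.48, with shuffled medians of 0.37 and 0.47). The intervals cover counting error only, and a consensus names a family of proteins and not the one bound.

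**Figure D3:**
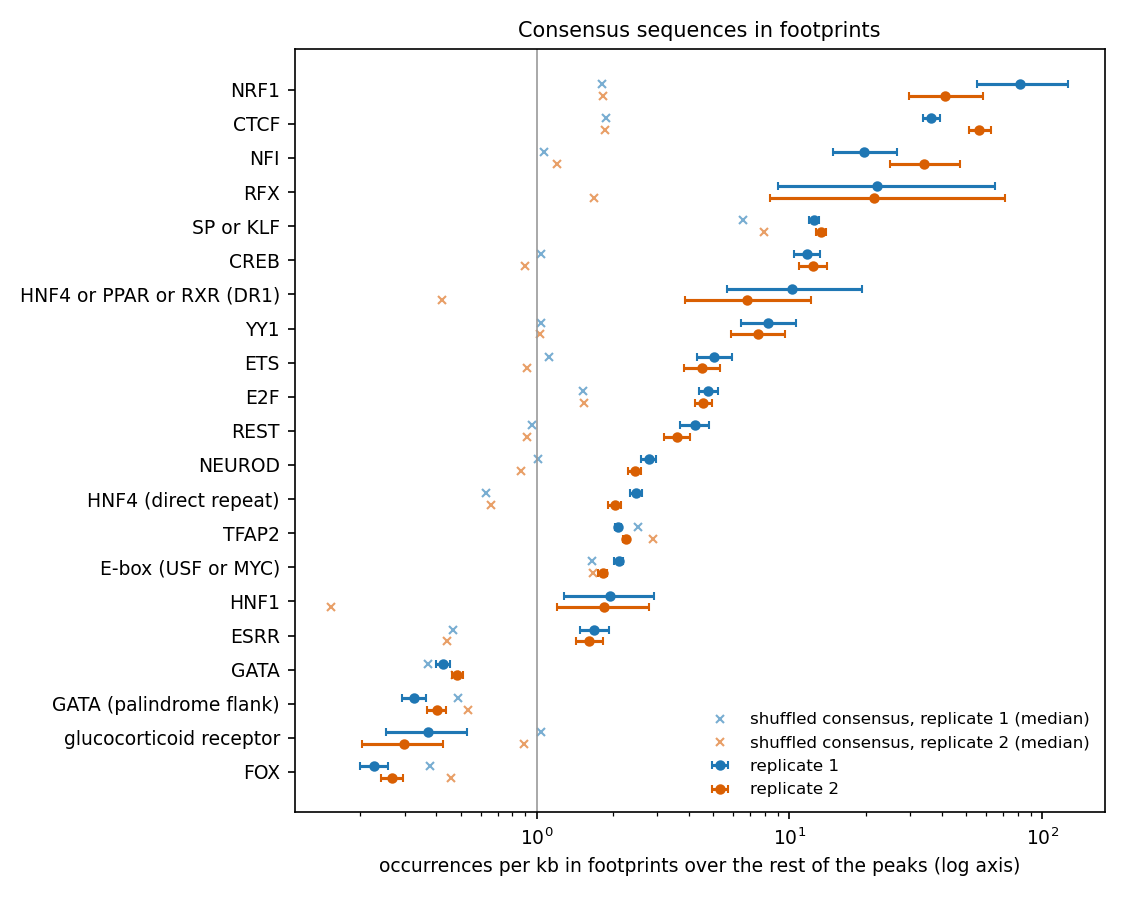
Occurrences per kb in footprints divided by occurrences per kb in peak bases outside footprints (log axis). Shown are the 17 sequences over 1.5 in both libraries and 4 of the 5 lowest, with Poisson 95% intervals. Crosses give the median of up to 10 shuffled versions (8 for SP or KLF), left out where it is 0. CTCF stands at 36.35 and 56.5, and the cross of TFAP2 lies to the right of its points.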

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

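The shorter lists for gene lists and the footprint counts without a replicate were chosen after seeing the data. Peaks per library fell to a mean of 132959 in the shorter lists. The promoter share was 12.66% with a 500 bp window, 22.66% with 2500 bp and 25.32% in the better-scored part, and the X ratio there was 0.225. Footprints shared with reciprocal overlap of 50% were 37.13%, and 66.3% lay in the shorter peak lists. Main values were 8 lists at or over the upper percentile and 3 at or under the lower for promoters, and 3 and 1 for distal regions. In the better-scored part, promoters gave 5 and 5. Lists at or under the lower bound were 6 with a 500 bp window, 9 without CpG matching and 5 in the shorter lists. For distal regions, 100 kb gave 1 list over the upper bound, the shorter lists 5, and the gene body alone 0 under the lower bound. The cause of these shifts was not tested. Without replicate 1 or 2, promoter lists over the upper bound numbered 6 or 7 and consensus sequences over 1.5 numbered 20 or 17. The podocyte list stood at percentile 95.05 without replicate 1 and 97.25 without replicate 2. The kidney transcription factor list stood at 97.34 without replicate 1. All members stayed open in these settings, so these percentiles were the highest possible and the bound could not be reached. The loss of those calls therefore reflects the random lists and not fewer open members. No paired analysis was possible because there is 1 group. Read depth is unknown, which limits what an absent peak means.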

Other observations

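What the HNF4, germ cell, exon and X chromosome tests would show was written before they were run, while the promoter shares of footprinted sites, the pick among the combinations of sequences and lists, and the bootstrap margin of the exon test came after the data were seen. Footprinted recognition sequences ranged from mostly promoter to mostly distal. Promoter shares were not computed for occurrences outside footprints or for shuffled sequences, so they are not separated from base composition. Among sites inside a footprint of both libraries, 92.6% of 163 YY1 sites (exact binomial 95% interval 87.5 to 96.1%), 77.95% of 263 ETS sites (72.4 to 82.8%), 76.8% of 453 NRF1 sites (72.7 to 80.6%) and 74.2% of 6914 SP or KLF sites (73.2 to 75.3%) lay within 1000 bp of a protein-coding start, against 31.2% of all 328779 stretches footprinted in both. CREB, NFY and E2F sites were also mostly at promoters (62.7%, 60.0% and 59.0%). TFAP2 sites (47.55% of 5867), E-boxes (38.9% of 2016) and IRF sites (30.8% of 312) lay between. At the other end, 4.28% of 795 MYOD-type sites, 5.03% of 5703 CTCF sites (4.48 to 5.63%), 5.88% of 255 NFI sites (3.33 to 9.52%), 6.98% of 1103 NEUROD-type sites, 7.35% of 177 ESRR sites (3.97 to 12.2%) and 10.4% of 1132 HNF4 sites (8.70 to 12.4%) were at promoters. The NEUROD-type sites may include CTCF sites, since some forms of the CTCF sequence contain theirs. AP-1 sites were at promoters in 10.4% of 537 cases and TEAD sites in 13.9% of 740.

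HNF4 is a regulator of proximal tubule genes, and the hypothesis that its footprinted sites gather around them was tested. A footprinted HNF4 consensus lay within the gene or 25 kb for 2 of 26 proximal tubule genes (7.69%). This was percentile 56.7 of random lists of the same gene lengths, so no excess was found. Those lists had a mean share of 7.31%, with bounds of 0 and 19.23%. With sites this sparse, a share well above that mean would still lie inside the bounds. The result therefore does not decide the hypothesis at this consensus and distance. Over 110 combinations of 5 sequences and 22 lists, the highest percentile was that of HNF4 sites around kidney transcription factor genes (7 of 27, percentile 99.8). Picked after the values were seen as the highest of 110, it was not tested further. ESRR around striated muscle genes reached 99.8 with 2 of 16 and HNF1 around podocyte genes 99.3 with 1 of 15.

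Few germ cell promoters were open. With a peak in either library the list still stood at percentile 0.02 (4 of 12). That value rests on peaks called at the same threshold of 0.05, below which these files hold no signal, so a threshold that hides weak signal and closed promoters cannot be told apart. Other genes, outside the list, were taken only by symbols that start with Sycp, Syce, Spata, Tssk, Tdrd or Tex and a digit. They also stood below all random lists in the share open in both libraries (38 of 86, percentile 0). Whether each of them is a germ cell gene was not checked. This was the outcome written beforehand for low accessibility of germ cell promoters in kidney, which stays a hypothesis, with the threshold left open. No other tissue was analysed here, so nothing shows that this is particular to kidney.

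Peaks found in replicate 2 alone were exonic more often than those found in replicate 1 alone (10.9% against 7.28%). Greater depth that adds weak, more often exonic peaks is argued against as the whole cause. Standardised to the score percentiles of the replicate 1 peaks the share was 10.53%, and standardised to their density it was 11.76%. It was also higher in the upper part of the replicate 2 scores (13.4%) than in the lower part (10.6%). The percentiles are ranks within each library and read depth is unknown, so other effects of depth are not excluded. Standardised to GC content the share was 9.147%, leaving 1.87 points (bootstrap 95% interval 1.57 to 2.20) of 3.67. The bootstrap resampled peaks, so its interval covers counting error only and not the spread between libraries. Within that limit, GC content may account for a part but not the whole of the difference between these 2 libraries. A difference in library preparation or sequencing stays open and was not tested, and the group gives no biological explanation to test.

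The X chromosome had 0.377 of the autosomal peak density. Gene density is argued against as the whole cause, since X has 0.6705 of the autosomal genes per Mb. A single X copy per male cell would lower the number of cuts. X promoter peaks had a mean median density of 0.5762 of autosomal ones of the same CpG decile. It was 0.602 (95% interval from resampled genes 0.531 to 0.649) in replicate 1 and 0.55 (0.488 to 0.601) in replicate 2. Distal X peaks had 0.496 and 0.493. Only genes with a called promoter peak enter the promoter ratios, 54.75% and 56.96% of X genes. Of autosomal genes of the same CpG deciles, 65.17% and 68.2% had such a peak. X promoters without a called peak are thus left out, which can raise the ratios. The bound written beforehand, 0.4 to 0.6 in both libraries, was narrowly missed in replicate 1. The single copy may contribute, and these values do not decide it.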
